A study of Homo sapiens with 1707 samples.

How the data were processed

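The measurements are single-cell transcriptomes of human breast cancer cells taken from mice that carried patient-derived xenografts, which are human tumours grown and passaged in immunodeficient animals. Per the labels' protocols, primary tumour, lung and lymph node tissue was dissociated with collagenase and trypsin, and red blood cells were lysed in lung and primary tumour suspensions. Viable single cells that carried the human surface protein CD298 and lacked mouse MHC class I were sorted into plates and converted to cDNA with Smart-seq2, a full-length protocol without molecular identifiers. Each of the 1707 deposited expression profiles is 1 cell. The labels name the tumour of origin, the mouse and the tissue of every cell, and these labels alone set the groups. The 3 tumours of origin are called models A, B and C here.

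Each deposited file gives FPKM values for 60155 gene identifiers, fragments per kilobase of transcript per 1e+06 mapped fragments. Per the submitters' processing notes, the authors used Bowtie2, RSEM and Seurat. Versions, the genome build and the annotation are not given in the sources used here. No genome coordinates are printed for that reason. Combined tables of the series hold the same values of all 1707 cells and were not used. Of the identifiers, 56531 matched GENCODE 29 and took their symbols from it. Left out everywhere were 561 identifiers, those on the Y chromosome, their pseudoautosomal copies, XIST and TSIX. Dropped cells and genes, and the scaling of each cell to its own total, can move the values that follow. A gene that takes a large part of a cell's total lowers the others.

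A gene counted as detected in a cell at an FPKM of 1 or more. Cells with at least 1000 detected genes were kept, which left 1447 cells (84.8%) and removed 260. No cell held values identical to those of another. Cells are not independent replicates, so the mouse was the replicate. FPKM values of each kept cell were rescaled to a total of 1e+06 and averaged over the cells of each mouse and tissue. The resulting 21 profiles are in units called scaled FPKM. FPKM keeps no total count, but the values of low genes step by whole fragments. Steps in FPKM times length over 4645 genes with a single transcript longer than 1500 nt gave an estimated depth per cell, and a median of 77.8% of the low values lay within 0.1 of a whole fragment. The median estimate was 368279 fragments per kept cell, and medians of the 21 profiles ran from 221150 to 802118. The estimates are approximate and served only as a covariate and a description.

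Genes were tested when their mean reached 5 scaled FPKM in at least 3 profiles, which left 11640. The test was limma's moderated test with a mean-variance trend (limma 3.58.1 under R 4.3.3) on log2(scaled FPKM + 1), with model and tissue as terms. A fold change on this scale understates the change of low genes. A second fit with a mean for each model and tissue gave the changes within a model, the test of whether changes differ between models and the test between models in primary tumours. P values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Errors given after log2 fold changes are standard errors, and errors after levels are standard deviations over mice. No deposited file holds counts, so no count model was run.

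The groups, tests, gene lists and alternatives were fixed before the data were examined, except 3 alternatives named as added in the closing section. The 27 lists cover the nuclear and the mitochondria-encoded subunits of oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, the hypoxia response, fatty acid oxidation, cholesterol synthesis, redox genes of NRF2, cytosolic ribosomal proteins and MYC targets in ribosome biogenesis. They also cover S phase, G2/M phase, immediate early genes, the unfolded protein response, the interferon response, NF-kB cytokines, basal, luminal, mesenchymal and mammary stem or metastasis genes, nuclear-retained RNAs and loading controls. Markers of fibroblasts and pericytes, immune cells, endothelium, lung epithelium and erythroid cells were listed as genes of other cell types. Host cells are mouse cells, so values per human gene cannot show whether the sort admitted any. Lists with at least 3 tested members, 23 in number, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. For each list the mean log2 difference between lung and primary tumour was also formed in each mouse and tested with an exact two-sided sign-flip permutation, whose smallest p with 9 mice is 0.0039. With 3 mice it is 0.25, so no such test was made for lymph nodes. Differences between models were tested by exact permutation of the model labels over the mice, 1260 arrangements in all.

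Named genes followed a rule. For lung against primary tumour, these are up to 10 genes of largest rise and 10 of largest fall among those past the threshold, with the same sign in at least 8 of 9 mice and a mean of at least 20 scaled FPKM in the higher tissue. A direction with under 5 was filled to 5 by smallest p, and such genes are said not to pass. For lymph nodes the limit was 5 genes per direction, filled to 3, and within a model it was 3, filled to 2, each with the same sign in every mouse. The rule adds 5 genes for the difference between models and up to 3 members of each list. Other named genes were chosen after their values were seen, and are said to be.

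Cell-to-cell similarity was the mean pairwise Spearman correlation between kept cells of 1 mouse and tissue over the 2000 genes of highest mean. The comparison was repeated on pairs of cells matched to within 10% of detected genes. Samples of 1 mouse are paired, because they come from the same animal by label. Deviations of lung and primary tumour from their group means correlated between 0.0097 and 0.478 across the 9 mice, and 7 of 9 lung profiles matched the primary tumour of their own mouse best. The 2 mice of model A are 1 outcome here, since deviations from a mean of 2 mirror each other. Matches were sought within a model only, so some arise by chance. A score per cell was the mean log2 level over a list's genes. For the hypoxia list it was also computed in primary tumour cells with all its genes divided by 1 factor per mouse, or each gene scaled to its mean in lung, both added after the results were seen. The fit with a block for mouse was an alternative. The cell titles carry a letter, T in primary tumours and H, I or L in metastases, whose meaning is not given and which was not used. The labels name no plate or library batch, so an effect of such a batch cannot be told from that of the tissue.

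The scripts were tested on simulated data with known changes in 100 genes per size among 11640. For lung against primary tumour 27% of genes changed by 1 on the log2 scale and 92% of those changed by 2 were recovered. For lymph nodes these shares were 5% and 50%, for model A 0% and 3%, for model B 0% and 20%, and for model C 4% and 53%. Between 0 and 3 unchanged genes were called in each simulated comparison. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and data.table in version 1.17.8. Alternatives covered the block for mouse, other ways to average cells, the pseudocount, gene and cell filters, other scalings, weights, covariates and leaving out each mouse in turn.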

Results

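Human breast cancer cells were compared between the primary tumour and the metastases that had formed in the same mice. The 9 mice carried 3 xenograft models, 2 mice of model A, 3 of model B and 4 of model C, and each model stands for 1 tumour of origin. Of the 957 cells from primary tumours 855 were kept, of the 654 from lung 511, and of the 96 from lymph nodes 81. Primary tumour and lung cells came from all 9 mice. Lymph node cells came from 3 mice, 12 kept cells from mouse 242 of model B, and 42 and 27 from mice 468 and 472 of model C. A kept cell had a median of 4594 detected genes and an estimated median of 368279 fragments. The share of mitochondria-encoded transcripts had profile medians from 5.4% to 44.5%. It was highest in the lung of mouse 470 at 44.5%, followed by the lymph node of mouse 242 at 43.1%. The lung of mouse 469 came next at 42.9%. The primary tumours of mice 470, 242 and 469 were at 21.9%, 21.7% and 20.2%. The lymph nodes of mice 468 and 472 were at 21.7% and 17.9%.

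The comparison of lung metastases with primary tumours asks which transcripts differ once the cells have settled in the lung. Genes of the hypoxia response and of glycolysis were lower in lung metastases. EGLN3 (ENSG00000129521.11), a hypoxia-induced prolyl hydroxylase that targets HIF for degradation, fell by 3.33 ± 0.43 on the log2 scale, from 41.9 ± 34.7 to 3.95 ± 4.31 scaled FPKM (SD, n = 9 mice each). It was lower in 9 of 9 mice with a limma adjusted p of 6.2e-04. BNIP3 (ENSG00000176171.9), a mitophagy receptor, fell by 2.39 ± 0.36, from 158.8 ± 153.4 to 19.4 ± 4.93 scaled FPKM, also in 9 of 9 mice. SLC2A1 (ENSG00000117394.17), which encodes the glucose transporter GLUT1, fell by 2.28 ± 0.37, from 195 ± 91.2 to 52.4 ± 47.2 scaled FPKM, in 8 of 9 mice. Of 11640 tested genes 36 changed, 6 upward and 30 downward, and 1285 had an unadjusted p under 0.05. The count was 1 with a trimmed mean over cells, 4 with log2 values averaged over cells, 8 without a gene filter and 15, 5 up and 10 down, with fragments per cell as a covariate.

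The 10 largest falls by the fixed rule ran from -3.33 to -2.08 on the log2 scale. Beside EGLN3, BNIP3 and SLC2A1 they were EDN2, an endothelin peptide precursor, at -3.25, CHI3L1, a secreted chitinase-like glycoprotein, at -2.93, NDRG1 at -2.56 and TMEM45A at -2.50. PFKFB3, which makes the activator of phosphofructokinase, was at -2.29, the endoplasmic reticulum oxidase ERO1A at -2.27 and the collagen prolyl hydroxylase P4HA1 at -2.08. Lower in all 9 mice but under the expression limit for named genes was MIR210HG, the host transcript of a hypoxia-induced microRNA, at -2.82 ± 0.39 (adjusted p = 9.2e-04), singled out after its value was seen. Fold changes of CHI3L1, PFKFB3 and ERO1A passed in 8, 13 and 14 of 27 alternatives, and with the block for mouse ERO1A had an adjusted p of 0.0525. The count of 36 was 13 without mouse 470, 13 without 472, 14 without 468, 18 without 257 and 22 without 259.

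**Figure D1:**
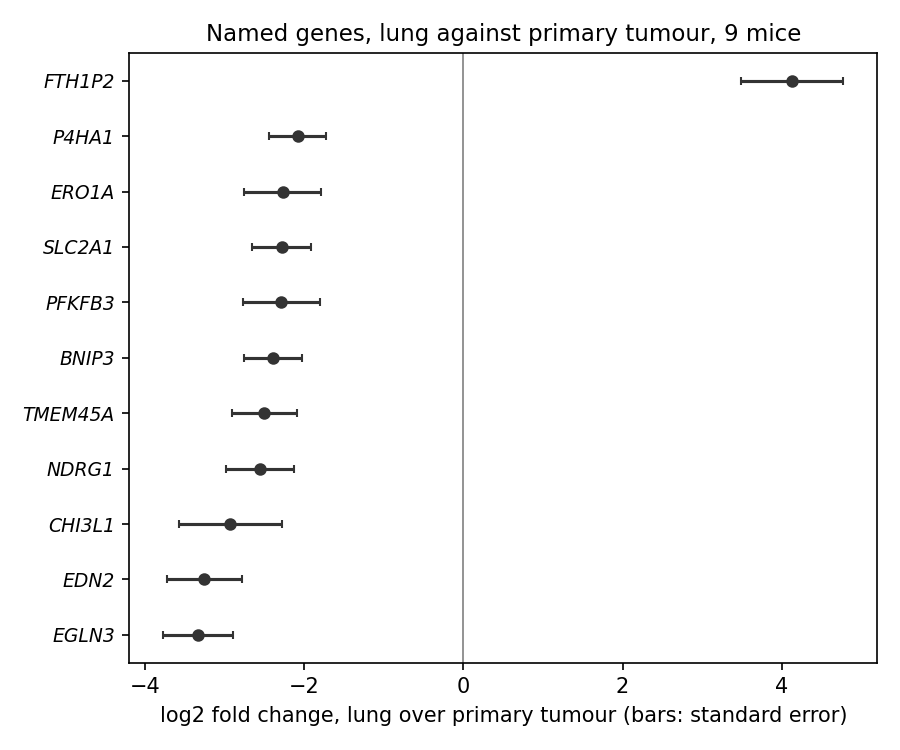
Log2 fold change of lung metastasis against primary tumour, with its standard error, for the 11 genes that passed and met the fixed rule in the 9 mice. EGLN3 lies lowest at -3.33 and the pseudogene FTH1P2 highest at 4.13.

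Of the 22 measured members of the hypoxia response list 8 fell and none rose, and 19 fell when adjusted over the list alone. The 8 were EGLN3, CA9, NDRG1, BNIP3, BNIP3L, P4HA1, ERO1A and ANGPTL4. CA9, a carbonic anhydrase at the cell surface, fell by 3.05 ± 0.47, from 18.4 ± 9.11 to 1.20 ± 1.45 scaled FPKM. The list's mean change was -1.56, and per mouse it was -1.56 ± 0.69 (SD), lower in 9 of 9 mice (exact sign-flip p = 0.0039, the smallest possible, and 0.0898 adjusted over 23 lists). The change was small in mouse 241, at -0.13, and lay between -2.37 and -1.15 in the other mice. Camera gave an adjusted p of 6.5e-26 at the preset correlation and 0.0017 with an estimated one. The list's mean fell under each of the 28 alternatives, between -1.83 and -1.01, and it was -2.00 in the 3 mice with lymph node cells alone, a setting not counted among them. Of the 23 glycolysis genes 4 fell, SLC2A1, LDHA, ALDOC and PFKFB3, and 20 fell when adjusted over the list alone. LDHA, the lactate dehydrogenase subunit, fell by 1.29 ± 0.25, from 1584 ± 813 to 585 ± 153.2 scaled FPKM. The list's mean per mouse was -1.05 ± 0.79 (SD), lower in 8 of 9 mice (exact sign-flip p = 0.0078, adjusted 0.0898). Its camera call held with an adjusted p = 0.0422 with an estimated correlation.

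Of the 77 nuclear-encoded genes of oxidative phosphorylation none passed, and their mean was -0.01 and their median 0.02. Their mean was 0.31 in model A, 0.17 in B and -0.31 in C, where 7 fell, and no test compared this list with the hypoxia list. Camera ranked the list above the other genes at the preset correlation (adjusted p = 0.0046), but not with an estimated correlation (adjusted p = 0.854). ATP5ME, an ATP synthase subunit, was at 0.41 ± 0.16 and higher in 9 of 9 mice, with an adjusted p of 0.327. The 13 mitochondria-encoded subunits had a mean of 0.36, none passed, and the camera call (adjusted p = 1.6e-07) was lost with an estimated correlation (adjusted p = 0.514). Per mouse they averaged 0.93 in model C, -0.24 in model A and 0.00 in model B. The median of all tested genes was -0.18 here, -0.08 when cells were rescaled without mitochondria-encoded genes and 0.00 after quantile normalization, and the split of calls was then 9 up and 19 down, and 11 up and 30 down.

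**Figure D2:**
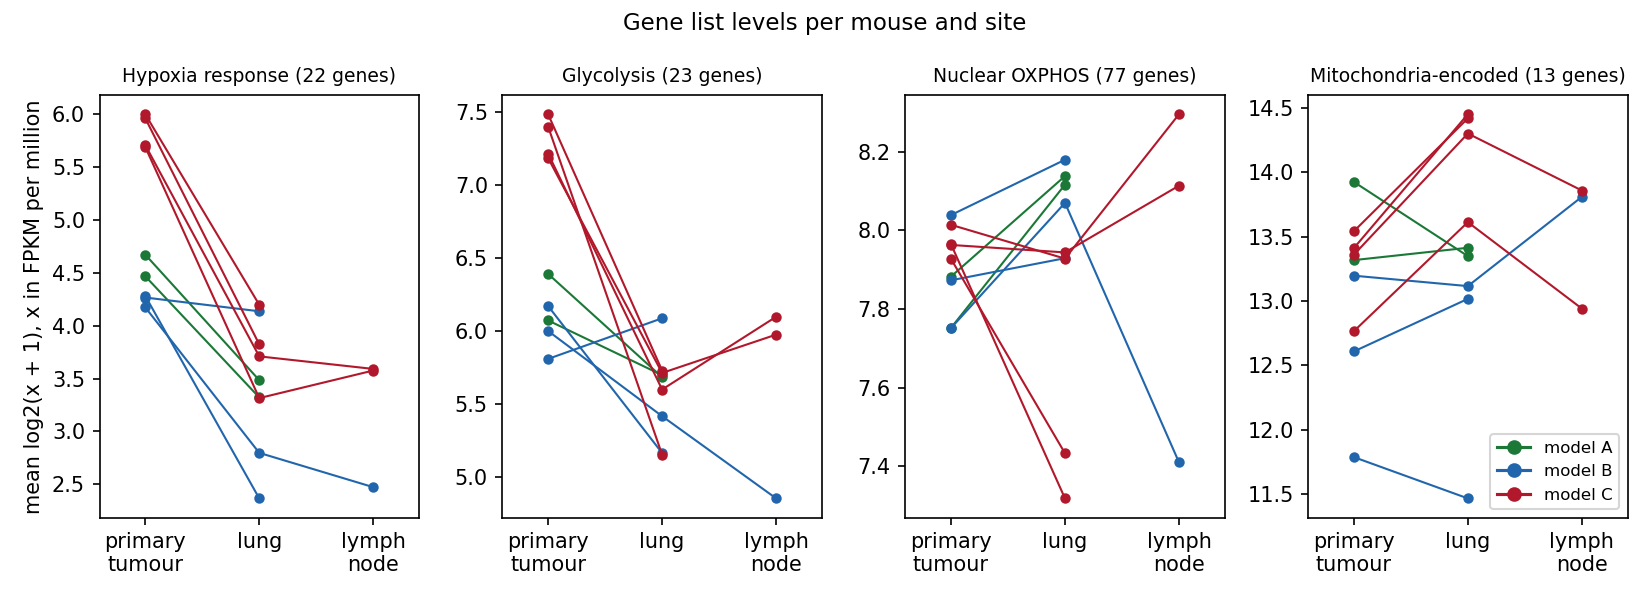
Mean log2(scaled FPKM + 1) over the tested genes of 4 lists in each mouse, with 1 line per mouse from primary tumour to lung and, in 3 mice, to lymph node, coloured by model. The hypoxia list of 22 genes is lower in lung in all 9 mice and the glycolysis list of 23 genes in 8 of 9, while the 77 nuclear-encoded oxidative phosphorylation genes are higher in 5 and lower in 4 mice.

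Other lists changed less. MYC targets of ribosome biogenesis had a mean of 0.25 with no member past the threshold, and ODC1, the first enzyme of polyamine synthesis, was at 0.79 ± 0.26 (adjusted p = 0.2501). Their camera call (adjusted p = 2.8e-07) had an adjusted p = 0.337 with an estimated correlation. S phase genes averaged 0.04 and basal epithelial genes 0.34, and their camera adjusted p were 0.658 and 0.538 with an estimated correlation. NF-kB cytokines averaged -0.76 and cholesterol synthesis genes -0.43, with 0.658 each by that test. CXCL3, a neutrophil chemokine, was the NF-kB member that fell, by 1.82 ± 0.37 (adjusted p = 0.0296). CLSPN of S phase, at 1.10 ± 0.28, and MSMO1 of cholesterol synthesis, at -1.19 ± 0.28, did not pass. Camera called none of the remaining lists. Mean changes were -0.20 for the tricarboxylic acid cycle, -0.29 for fatty acid oxidation, -0.16 for redox genes of NRF2, -0.04 for ribosomal proteins, -0.20 for G2/M phase and -0.36 for immediate early genes. They were -0.28 for the unfolded protein response, -0.44 for interferon genes, -0.19 for luminal, -0.48 for mesenchymal and -0.06 for mammary stem or metastasis genes. Nuclear-retained RNAs averaged -0.24 and loading controls -0.31. FOS, the immediate early gene of smallest p after adjustment, was at -1.25 ± 0.28 with an adjusted p of 0.0502, and the block for mouse gave 0.0336.

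Markers of other cell types were looked at as lists. A host cell would be a mouse cell, so neither low nor changed values of these human genes show how many were admitted. Fibroblast and pericyte markers had a mean of -0.68, with none of 8 past the threshold and no camera call (adjusted p = 0.224). Their mean was 0.43 in model A, 0.61 in B and -2.21 in C, where 4 fell, and PDGFRA was at -1.32 ± 0.42 (adjusted p = 0.227). Fewer than 3 markers could be tested for the others. The most abundant immune marker, CD74, averaged 12.2 ± 26.7 scaled FPKM in primary tumours and 14.5 ± 37.8 in lung, and the endothelial marker ESAM 2.53 and 4.11. The lung epithelium marker ABCA3 averaged 3.75 and 1.54, and HBB, the haemoglobin beta chain, 0.955 and 7.92.

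The 6 rises in lung were mostly of processed pseudogenes, intronless copies of highly expressed genes whose reads cannot be separated with certainty from those of their parents. FTH1P2 (ENSG00000234975.6), a copy of the ferritin heavy chain gene, rose by 4.13 ± 0.64, from 0.479 ± 0.619 to 68.5 ± 84.2 scaled FPKM (adjusted p = 0.0020), in 9 of 9 mice. It was detected in 8.87% of lung and 2.26% of primary tumour cells, averaged over profiles. PPIAP40 rose by 2.75, FTH1P16 by 2.50, PPIAP9 by 1.92 and UBBP3 by 1.68, and these 4, with the histone gene HIST1H2AL at 1.98 ± 0.42, were named after their values were seen. EIF5 at 0.72 ± 0.19, ORC6 at 0.93 ± 0.28 and DANCR at 0.74 ± 0.23 were among the genes that fill the rule's rises, and did not pass. FTH1P2 passed in 22 of 27 alternatives. It did not pass with log2 values averaged over cells, with a trimmed mean, without a gene filter, in cells with at least 2000 detected genes, or without the cells that held pseudogenes of 2 parent genes. The last setting removed cells chosen by FTH1P2 among other pseudogenes, so a weaker rise follows from that choice.

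The fall of the hypoxia list was also looked at cell by cell, after the list result had been seen. A score per cell, the mean log2 level over the list's genes, was lower in lung at the 90th percentile of cells by a mean of -1.88 ± 1.07 (SD), in 9 of 9 mice (exact sign-flip p = 0.0039). The median cell differed by -0.87 ± 0.82 in 8 of 9 mice (exact p = 0.0156), and the 10th percentile by -0.55 ± 0.74 in 6 of 9 (exact p = 0.0781). Genes listed at 0 in a cell cannot fall, and dividing all hypoxia genes by 1 factor per mouse also lowered the 90th percentile more than the median in 9 of 9 mice, so the size of these differences cannot be compared directly between percentiles.

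**Figure D3:**
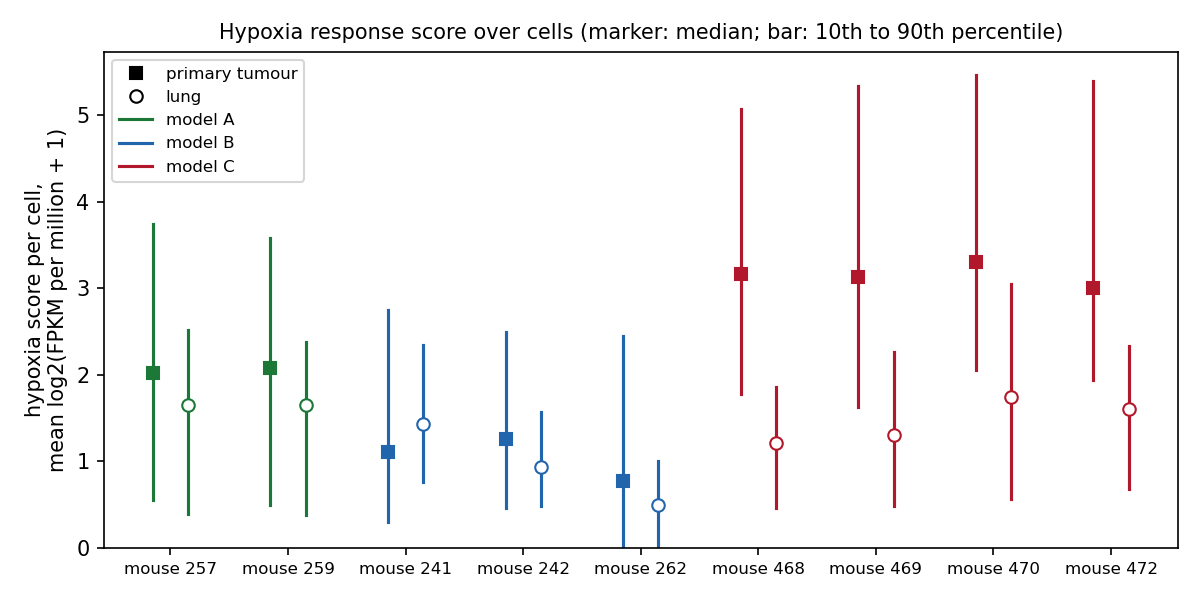
Score of the hypoxia response list per cell in each mouse, as mean log2 level, for primary tumour and lung. Bars span the 10th to the 90th percentile of kept cells and points mark the median. The upper end is lower in lung in 9 of 9 mice.

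Lymph node metastases were set against primary tumours with the same question, with 3 lymph node profiles. Genes of the hypoxia response were lower. EDN2 was listed at 0 in all 3 lymph node profiles and averaged 63.1 ± 43.9 scaled FPKM in the 9 primary tumours (adjusted p = 1.7e-04). An identifier of the RNA family RF00004 was also listed at 0 there, against 54.6 ± 71.5 (adjusted p = 0.0450). The other identifiers of that family did not pass, so its reads cannot be placed with certainty. ANGPTL4, an inhibitor of lipoprotein lipase, fell by 3.83 ± 0.51, from 61.03 ± 56.69 to 6.49 ± 5.67 scaled FPKM. EGR2, an immediate early transcription factor, fell by 4.29 ± 0.73 and TGFBI, a secreted matrix protein, by 4.10 ± 0.87, each in 3 of 3 mice. In all 75 genes fell and 0 rose, and 1774 had an unadjusted p under 0.05. CCND3 at 1.48 ± 0.43, GEMIN6 at 1.36 ± 0.41 and PCBD1 at 0.92 ± 0.28 had the smallest p among rises and did not pass.

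Of the 22 hypoxia genes 8 fell in lymph nodes, and 16 when adjusted over the list alone. ADM, the peptide hormone adrenomedullin, fell by 3.72 ± 0.70 and P4HA1 by 3.03 ± 0.52. The list averaged -1.99 in the fit and -1.98 ± 0.24 (SD) over the 3 mice, with a camera adjusted p of 3.5e-16 and of 0.0166 with an estimated correlation. Of 23 glycolysis genes LDHA, at -1.69 ± 0.36, and SLC2A1, at -2.47 ± 0.54, fell, and 10 fell when adjusted over the list alone. Of 20 cholesterol synthesis genes MSMO1, MVD and INSIG1 fell, to log2 fold changes of -2.15, -1.96 and -2.07, and 4 fell when adjusted over the list alone. None of these 3 passed with the block for mouse, and the camera call had an adjusted p = 0.528 with an estimated correlation. Collagen gene COL3A1 was the 1 of 8 fibroblast and pericyte markers that fell, by 3.39 ± 0.69, and 6 fell when adjusted over the list alone. TGFBI was the 1 of 22 mesenchymal genes, and 8 fell when adjusted over the list alone. Camera called these 4 lists at the preset correlation only. With an estimated correlation the adjusted p were 0.411 for glycolysis, 0.411 for fibroblast and pericyte markers and 0.495 for mesenchymal genes. The unfolded protein response, with a mean of -0.63, had an adjusted p = 0.570 by that test. Nuclear and mitochondria-encoded oxidative phosphorylation genes, at 0.05 and 0.41, ribosomal proteins at 0.07, MYC targets at 0.08 and S phase genes at 0.11 were also called at the preset correlation only. Their estimated values were adjusted p of 0.692, 0.528, 0.692, 0.692 and 0.570. Mean changes of lists without a camera call were -0.34 for the tricarboxylic acid cycle, -0.27 for fatty acid oxidation, -0.09 for redox, -0.22 for G2/M, -0.70 for immediate early, -0.46 for interferon, -0.68 for NF-kB and -0.15 for basal genes. They were -0.46 for luminal, -0.23 for stem or metastasis genes, -0.68 for nuclear-retained RNAs and -0.35 for loading controls.

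With the block for mouse 2 genes passed in lymph nodes, EDN2 and ANGPTL4, and quantile normalization gave 2 up and 17 down. No gene passed with log2 values averaged over cells or with a 10% trimmed mean. The median fold change of all tested genes was then 0.045 and 0.015, against -0.31 in the main fit. Without 1 mouse the count was 3 for 242, 13 for 470, 22 for 472, 30 for 257, 31 for 469, 36 for 468, 43 for 259 and 339 for 262.

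Of the genes that fell in lymph nodes 11 also fell in lung, namely NDRG1, CA9, SLC2A1, P4HA1, EDN2, EGLN3, LDHA, SERPING1, ANGPTL4, BNIP3 and MIR210HG, against 0.193 expected of independent lists. Both comparisons used the same primary tumours and lung and lymph node share mice. With the block for mouse at most 2 of these can be shared, since EDN2 and ANGPTL4 alone passed in lymph nodes. Across genes, which are not independent replicates, the fold changes correlated with r = 0.495, against a mean of 0.310 and a highest value of 0.651 in 100 simulations without change. Their covariance was 0.130, against a simulated mean of 0.0398 and a highest of 0.103, and no gene fell in both in a simulation. With the primary tumours split between the comparisons r had a median of 0.268 over 50 splits and the shared falls a median of 0. Lung profiles stayed in both fits of a split, so the comparisons were not fully separated. The simulations shuffled deviations over all profiles and so lack what tissues of a mouse share. An excess over them can therefore not be credited to the metastases alone.

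Between lymph node and lung metastases limma called 0 genes, and 874 had an unadjusted p under 0.05. The hypoxia gene ANGPTL4 was at -2.13 ± 0.51 (adjusted p = 0.237) and COL3A1 at -3.01 ± 0.69 (adjusted p = 0.227), both lower in lymph node in 3 of 3 mice. Without mouse 468 the count was 5, and without 242 or 472 it was 1.

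The 3 models were then taken separately, since each is a different tumour. In model C most genes of the glycolysis and hypoxia lists were lower in lung metastases than in primary tumours, and smaller parts of other lists were. No test of a list as a set was run within a model. STC1, a secreted glycoprotein hormone, fell by 4.77 ± 0.84, from 63.4 to 5.76 scaled FPKM, and CHI3L1 was at -4.75 ± 0.90 and ACTA2, smooth muscle actin, at -4.58 ± 0.89, each in 4 of 4 mice. Of 23 glycolysis genes 19 fell, and 22 when adjusted over the list alone, and SLC2A1 was at -3.72 ± 0.41, LDHA at -2.02 ± 0.24 and PGK1 at -1.97 ± 0.27. Of 22 hypoxia genes 15 fell, and 19 over the list alone, with BNIP3 at -3.73 ± 0.41 and HILPDA, a lipid droplet protein, at -2.66 ± 0.35. Of 43 G2/M genes 8 fell, among them NUF2 of the kinetochore at -1.81 ± 0.38 and TPX2 of the spindle at -1.43 ± 0.34. Mesenchymal genes had 5 of 22 falls, with the gelatinase MMP2 at -2.50 ± 0.45 and vimentin, VIM, at -1.15 ± 0.27. Fibroblast and pericyte markers had 4 of 8, with LUM at -3.49 ± 0.93 and FAP at -1.58 ± 0.42 beside ACTA2. Of 17 genes of the tricarboxylic acid cycle 5 fell, with IDH2 at -1.56 ± 0.26. Of 20 cholesterol synthesis genes 5 fell, with MSMO1 at -1.99 ± 0.36, and of 15 fatty acid oxidation genes 4, with HADHA at -1.35 ± 0.28. Of the 77 nuclear oxidative phosphorylation genes 7 fell, with UQCRC2 at -1.18 ± 0.27, while MT-ND2 was the 1 of 13 mitochondria-encoded genes that rose, by 1.02 ± 0.27. ACTB and PGK1, among 10 loading controls, fell too.

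In model C 771 genes changed, 28 upward and 743 downward. The count was 29, all down, with fragments per cell as a covariate, 63, 4 up and 59 down, in cells with at most 30% mitochondria-encoded transcripts, and 1.6e+02, 8 of them up, with detected genes as a covariate. The rises named by the rule were the antisense transcript AC011603.2 at 3.30 ± 0.51, the long noncoding RNA Z93241.1 at 2.85 ± 0.78 and the histone gene HIST1H3C at 2.75 ± 0.77, and antisense reads cannot be told from those of the partner gene without strand. The median of all tested genes was -0.46, and it was -0.17 when rescaled without mitochondria-encoded genes and 0.01 after quantile normalization. The calls were then 301 after the first, 1.1e+02 up and 1.9e+02 down, and 1.7e+02, with 80 up and 93 down, after the second, and with the block for mouse they were 2038 with 1933 down. The count was 1.6e+02 without mouse 470, 200 without 472, 259 without 468, 260 without 469, 337 without 259, 345 without 257, 1296 without 241 and 1530 without 262.

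In model B 13 genes changed, 10 upward and 3 downward, and 23 with the block for mouse, 14 up and 9 down. FTH1P2 rose by 6.81 ± 0.74, FTH1P16 by 4.75 ± 0.66 and PPIAP40 by 4.64 ± 0.67, each in 3 of 3 mice and each a pseudogene. Without the 15 cells that held pseudogenes of 2 parent genes 4 genes passed, 1 upward and 3 downward. Those cells were chosen by their levels of these same pseudogenes, so weaker rises of them follow from the choice. EGLN3 fell by 4.37 ± 0.75 and MFAP4, a microfibril protein, by 4.11 ± 0.65. EGLN3 was the 1 of 22 hypoxia genes that passed, and 3 fell when adjusted over the list alone. The count was 53 without mouse 241 and 4 without 262. In model A, with 2 mice, limma called 0 genes and 1.7e+02 had an unadjusted p under 0.05. The hypoxia gene ANKRD37 was at -2.09 ± 0.58, the milk protein gene LTF at -3.53 ± 0.98, the protease gene KLK7 at 1.89 ± 0.43 and FTH1P2 at 4.55 ± 0.91, and none passed. Of its 22 hypoxia genes 5 fell when adjusted over the list alone. Without mouse 262 of model B, which shares in the spread of the fit, 2 genes passed in model A.

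The hypoxia list averaged -1.17 ± 0.03 per mouse in model A, -1.14 ± 0.92 in B and -2.08 ± 0.24 in C (SD), and the models did not differ by exact permutation (adjusted p = 0.201). On the scale fixed in advance they differed in 2 lists. Mesenchymal genes averaged 0.30 ± 0.05 in A, 0.01 ± 0.30 in B and -1.24 ± 0.28 in C (exact permutation p = 0.0032, adjusted 0.0365). Redox genes of NRF2 averaged 0.31, -0.07 and -0.47 (exact p = 0.0024, adjusted 0.0365). Nuclear oxidative phosphorylation genes averaged 0.31, 0.17 and -0.31 (exact p = 0.0468, adjusted 0.0913). The median of all tested genes moved between models as well, at 0.16 ± 0.08 per mouse in A, -0.02 ± 0.04 in B and -0.45 ± 0.03 in C (exact p = 7.9e-04). Relative to it, on a scale added after the lists had been seen, redox genes averaged 0.16, -0.04 and -0.03 (exact p = 0.471) and mesenchymal genes 0.14, 0.04 and -0.79 (exact p = 0.0127, adjusted 0.146). No list differed between models after adjustment on that scale, where the smallest adjusted p was 0.0913. By limma's test of the difference between models 1 gene passed and 1153 had an unadjusted p under 0.05. LY6G6C, a surface protein of the LY6 family, was at -3.31 ± 0.40 in B, 0.19 ± 0.49 in A and 0.21 ± 0.35 in C (adjusted p = 0.0327). PPIAP9, UCP2, UBBP3 and COMP followed with adjusted p of 0.109, and the block for mouse left 0 genes. The count was 27 without mouse 241, 3 without 469 and 0 without any 1 of the other 7 mice.

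Primary tumours of the 3 models differed in 4787 genes, which describes these 3 tumours only. Their cells also differed in detected genes, with 5868 ± 13.4 in A, 3310 ± 1089 in B and 5921 ± 642 in C (SD over mice), and lower list levels in B cannot be separated from this. All 8 fibroblast and pericyte markers differed, with list levels of 1.02 ± 0.14 in A, 1.72 ± 0.44 in B and 5.34 ± 0.14 in C on the log2 scale. Mesenchymal genes differed in 20 of 22, with levels of 3.40, 4.16 and 6.30. G2/M genes differed in 39 of 43, and model B was lowest at 2.75 ± 0.48, against 4.82 in A and 5.66 in C. S phase genes followed with 25 of 32 and levels of 4.95, 3.05 and 5.03. Luminal genes differed in 14 of 16, with the highest level, 8.09 ± 0.38, in A, and cholesterol synthesis genes in 16 of 20, with the lowest, 3.46 ± 0.57, in B. Hypoxia genes differed in 11 of 22 and were highest in C, at 5.84 ± 0.16.

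The series names transcriptional diversity as a subject, and it was measured as the similarity between cells of 1 mouse and tissue. Similarity was 0.497 ± 0.047 in lung and 0.505 ± 0.053 in primary tumours (SD, n = 9), and the difference within mice of -0.0086 ± 0.0730 was smaller than its spread (exact sign-flip p = 0.723). It was higher in lung in all 5 mice of models A and B and lower in all 4 of C, and the models did not differ after adjustment (exact permutation p = 0.0437, adjusted 0.0655). Detected genes per cell were likewise higher in lung in these 5 mice and lower in these 4, and the measure moves with them. Cells matched on detected genes gave 0.0126 ± 0.0331 (exact sign-flip p = 0.383). By model these were -0.0080 in A, 0.0032 in B and 0.0298 in C (exact permutation p = 0.370). Over all kept cells the difference was 0.0064 without mouse 469 and 0.0047 without 470. In the lymph nodes of mice 242, 468 and 472 similarity was 0.507, 0.584 and 0.666.

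The number of genes detected per cell did not differ between lung and primary tumour over all mice, with a mean difference of -425.3 ± 1273 genes (SD, n = 9, exact sign-flip p = 0.320). It did differ between models, with 642 ± 92.99 more genes in lung in A, 595 ± 545 more in B and a difference of -1724 ± 262 in C (exact permutation p = 0.0071, adjusted 0.0214).

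**Figure D4:**
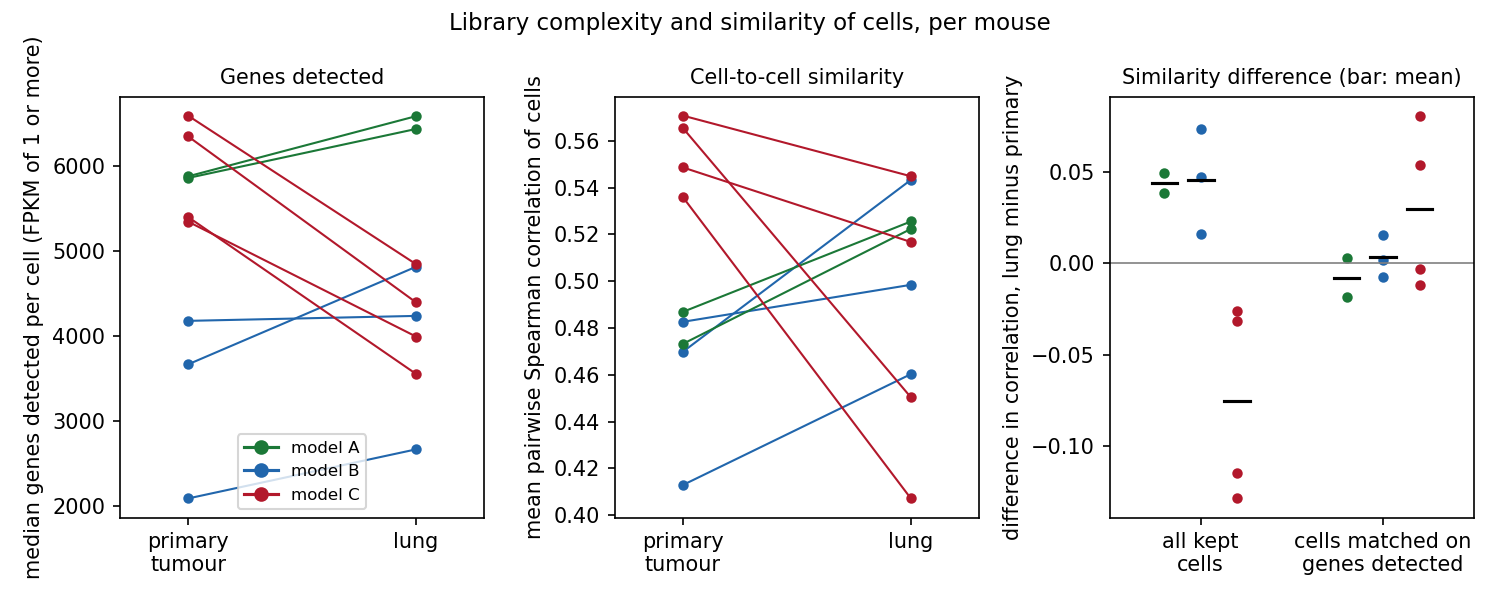
Median number of genes detected per cell and mean Spearman correlation between cells, with 1 line per mouse from primary tumour to lung coloured by model, and the lung minus primary difference in correlation for all kept cells and for cells matched on detected genes. In the last panel points are mice and bars are model means, and model C lies at -0.0754 in all cells and at 0.0298 in matched cells.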

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

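For the fall of the hypoxia list in lung, the test on damaged cells was chosen before its own result was seen. Its filter of cells, though, was added after the data were seen. The tests on depth and on the mitochondria-encoded share were chosen after the result was seen. The rescaling itself was an alternative fixed in advance. The list's mean was -1.42 with fragments per cell as a covariate, -1.41 when rescaled without mitochondria-encoded genes and -1.66 in cells with at most 30% mitochondria-encoded transcripts. Each stays far below the -0.5 that these 3 explanations required, so none of them accounts for the fall. A difference in plates or in the handling of the tissues stays open. The labels give the same enzymes for all tissues, but no plate, library batch or day of dissociation. The tissue itself, through oxygen supply or lesion size, stays open as well, since neither was measured.

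For the pseudogene rises in lung, both tests were chosen after the result was seen. A higher level of the parent genes FTH1, PPIA and UBB in all cells does not account for them, since the parents' median log2 fold change was -0.047. Parents without a rise cannot show whether a small part of their reads was counted on the pseudogenes. Shared reads as such therefore stay open. Pseudogenes of at least 2 parents met in 13 of 511 lung cells, from 8 mice and all 3 models, against a mean of 3.999 and a highest of 12 in 10000 shuffles within profiles. They met in 2 of 855 primary tumour cells. These pseudogenes were picked as higher in lung, so fewer such primary tumour cells follow from that choice. RNA from another source than the tumour genome in a few cells may explain the meeting in lung cells. The 13 lung cells had a median EPCAM of 6.10 against 293 scaled FPKM in other lung cells, KRT18 of 158.6 against 358.7, KRT8 of 756 against 790, KRT19 of 999 against 855 and 3094 against 4410 detected genes. FTH1 was higher in them, at 4923 against 2154, and PPIA and UBB lower, at 2431 and 11.9 against 3024 and 26.3, so reads shared with FTH1 in these very cells stay open. Epithelial markers thus went both ways. All these medians pool cells over mice and models without matching, so differences between models can enter them. Mouse RNA, from the host tissue that the sort was set to exclude, is a candidate that values per human gene cannot test. The sources do not say whether reads were aligned to the human genome alone or together with that of mouse, which decides whether mouse reads can be counted on human pseudogenes.

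For the one-sided fall in model C, both tests were chosen after the result was seen. The median log2 fold change of all tested genes moved from -0.46 to -0.17 when rescaled without mitochondria-encoded genes, and to -0.19 with fragments per cell as a covariate. Neither reached 0 nor stayed at its first value, so each explanation could account for a part of the fall and neither is decided. Lung cells of this model also differed by -1724 in detected genes.

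For the grouping by tissue, all tests were chosen before the result was seen. The splits counted include the real one. For the 36 genes of lung against primary tumour 1 of 100 splits, the real one, had as many and the highest other gave 2. Splits within mice gave at most 1 otherwise. In both sets the share is the smallest that 100 splits can give. Chance is thus unlikely for this count in the main fit, but not excluded. For the 771 genes of model C 1 of 35 splits, the real one, had as many and the highest other gave 6. That is the smallest share that 35 splits can give, and they do not keep the tissues of a mouse together. The block for mouse gave 2038 genes there, so chance is unlikely for model C but not excluded by the splits. For the 75 genes of lymph node against primary tumour 1 of 100 splits had as many and the highest other gave 5, but these splits do not keep the tissues of a mouse together. The block for mouse left 2 of these calls, the mice with lymph node cells alone gave 2 and leaving out mouse 242 gave 3, so chance stays open there. Chance cannot be excluded for the number of gene lists. The 9 lists of lung were matched or passed in 35 of 100 splits, with a highest of 14, and in 37 of 100 within mice, with a highest of 16. The 11 lists of lymph node were matched or passed in 18 of 100, with a highest of 15. For lymph node against lung the real count was 0, so all 100 splits had to match it, and the highest of 45 decides nothing. Splits within mice for lymph node, 8 in all with 75 genes for the real one and 0 for the highest other, were too few to decide. So were the 10 splits of model B, where 3 had at least the real 13 genes. The highest of these, with 1573 genes, set both tissues of mouse 241 and the primary tumour of 242 against the rest, which points to structure between mice.

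Some values differed between models. Detected genes in lung minus primary tumour did so with an adjusted exact permutation p of 0.0214, LY6G6C with a limma adjusted p of 0.0327, and the mesenchymal and redox lists with adjusted exact permutation p of 0.0365 and 0.0365. Relative to the median of all genes in each mouse, tested after these were seen, the adjusted permutation p were 0.146 for the mesenchymal and 0.731 for the redox list. A shift of all genes is not set apart from the redox difference. The mesenchymal list stayed at -0.79 ± 0.31 (SD) in C, against 0.14 ± 0.12 in A and 0.04 ± 0.28 in B. These values argue against a shift of all genes as its only source, although the difference between models did not pass adjustment. Single mice stood apart in 5 of 50 sets of values, and about 1 in 20 would by chance. P4HA1 was at 0.67 in mouse 241 and between -3.77 and -1.53 in the others, and PFKFB3 was at 0.24 in mouse 241 and between -3.88 and -1.88 in the others. TMEM45A was at -6.07 in mouse 262 and between -2.99 and -0.52 in the others. Kept cells were 37.5% in the lung of mouse 469, against 70.8% to 100% elsewhere, and 67.9% in the primary tumour of mouse 468, against 85.4% to 98.8%. A single mouse or library explains such a value as well as biology does.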

How the results depend on the processing

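Counts are given in the order in which comparisons were met and the cause of each move was not tested. With the block for mouse, lymph node against primary tumour had 2 genes, model B 23, model C 2038 and the difference between models 0. The block also ended the calls of ERO1A in lung and of RF00004, EGR2, TGFBI, LDHA, SLC2A1, P4HA1, ADM, MSMO1, MVD, INSIG1 and COL3A1 in lymph node, and added FOS, EGR2 and BTG2 in lung, TTK and RGS5 in model B, and MT-CO2, MT-ND3, SOD2, RPL3, RPL4, NOP16, PDIA6, PSMB9, CXCL1, SAA1, SFN, CLDN4, PROCR and EEF1A1 in model C. It changed no other call of a named gene and no list call. Log2 values averaged over cells gave lung 4, lymph node 0, model A 9, model B 1, model C 3195 and the difference between models 581. A 10% trimmed mean gave 1, 0, 25, 8, 1394 and 1.8e+02 for the same. A pseudocount of 0.1 gave lung 17, lymph node against lung 3, model A 1 and the difference between models 0, and of 10 gave lymph node 26, model A 4, model B 20 and the difference 41. Without a gene filter lung had 8, lymph node 10, lymph node against lung 4, model A 204, model B 72, model C 449 and the difference 1.8e+02. A filter at 20 gave model B 4 and the difference 0. Cells with at least 500 genes gave lung 57, model A 1, model C 1534 and the difference 0, and with at least 2000 lymph node 1.2e+02, lymph node against lung 3, model A 1, model B 3 and model C 242. Without rescaling lymph node had 36 and model C 336. Rescaled without mitochondria-encoded genes lymph node had 36, lymph node against lung 4, model C 301 and the difference 0. Quantile normalization gave lymph node 19 and model C 1.7e+02. Array weights gave lung 140, lymph node 1.4e+02, lymph node against lung 1, model A 58, model B 36, model C 1216, the difference 80 and the models in primary tumours 7670. At least 20 cells per profile gave lymph node 4 and lymph node against lung 1. Detected genes as a covariate gave lymph node 275, model C 160 and the difference 0. Of the alternatives added after the data were seen, fragments as a covariate gave lung 15, model C 29 and the difference 0. Cells with at most 30% mitochondria-encoded transcripts gave lymph node 23, lymph node against lung 1, model A 1, model C 63 and the difference 3. Without cells that held pseudogenes of 2 parents, which were chosen by genes that had risen, model A had 1 and model B 4. With the mice that gave lymph node cells alone, lymph node had 2. With an estimated correlation camera called 2 lists in lung and 1 in lymph node. The combined-table alternative gave no value, since those tables hold all 1707 cells.

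By camera's direction, signs reversed in a few results, and means of other lists in lymph node crossed 0 as well. G2/M genes ran from -0.54 to 0.57 and were called up in 6 of 29 alternatives, MYC targets from -0.12 to 0.57 with 22 of 29 called and ribosomal proteins from -0.03 to 0.19 with 25. Basal genes, from -0.60 to 0.44, and luminal genes, from -0.75 to 0.27, were called in none. In lymph node the mitochondria-encoded list was at -0.15 with at least 20 cells per profile, and the interferon list was called down at -1.01 there, at -1.02 in cells with at most 30% mitochondria-encoded transcripts and at -1.11 without mouse 242, and was at 0.14 without 468. HIST1H3C in model C was at -0.76 in cells with at most 30%. Similarity was 0.0048 in cells with at least 2000 genes, 0.0126 in matched cells, 0.0064 without mouse 469 and 0.0047 without 470. Leaving out each mouse in turn gave lung 13 to 42 genes, lymph node 3 to 339, lymph node against lung 0 to 5, model A 0 to 2, model B 4 to 53, model C 1.6e+02 to 1530, the difference between models 0 to 27 and the models in primary tumours 3585 to 5000. It gave 8 to 11 lists in lung, 9 to 13 in lymph node, detected genes of -622 to -234 and similarity of -0.0188 to 0.0064. Model A has 2 mice and lymph node 3, and FPKM carries no counts, so small changes there could go unseen, and low genes are limited by a median of 368279 fragments per cell.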

Other observations

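Whether the lower hypoxia level in lung is a loss of the highest-scoring cells of the primary tumour or a shift of all cells was not decided by the tests. In model C the levels given below argue against a loss of the highest-scoring cells alone. All 3 forms of the test were chosen after the list result was seen, the last 2 after the first. The difference at the 90th percentile of the hypoxia score exceeded that at the median by -1.02 ± 0.34 (SD) in 9 of 9 mice (exact sign-flip p = 0.0039, the smallest possible), while for glycolysis it was -0.21 ± 0.48 (exact p = 0.219). Genes listed at 0 in a cell cannot fall, and dividing all hypoxia genes of all primary tumour cells by 1 factor, set to meet the 90th percentile of lung, also gave a negative contrast in 9 of 9 mice, with a mean of -0.72. The sign of the contrast is therefore fixed and the first form is void. Against that factor the median in lung was higher than expected by 0.29 ± 0.16 in 9 of 9 mice (exact p = 0.0039). With a factor per gene, set to meet its mean in lung, the median differed from the expected by -0.15 ± 0.36, higher in 5 mice and lower in the 4 of model C (exact p = 0.246), while the contrast differed from the expected by -0.53 ± 0.30 in 9 of 9 (exact p = 0.0039). Neither factor models genes that drop out of detection, and the forms disagree on the median. In model C the 10th percentile fell too, from 1.78, 1.63, 2.06 and 1.94 to 0.46, 0.49, 0.56 and 0.68 in its 4 mice. The median in lung, at 1.21, 1.31, 1.74 and 1.61, lay below that 10th percentile of primary tumour cells in each of the 4. A loss of the highest-scoring cells alone would not give this. Lung cells of model C also had fewer detected genes, so a shift of all cells is not shown by it. In models A and B the 10th percentile went from 0.55, 0.50, 0.30, 0.46 and 0 to 0.39, 0.38, 0.76, 0.49 and 0. Staining of CA9 and EGLN3 on sections of both tissues would show which cells differ, with lesions ordered by size.

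Across primary tumour cells of model C the mesenchymal score ran against the luminal score, also tested after the result was seen. With detected genes removed, Spearman rho was -0.352, -0.466, -0.320 and -0.360 in its 4 mice, the highest being -0.32. It was 0.560 and 0.508 in model A and 0.0016, -0.038 and 0.090 in model B. Without that removal it was between -0.229 and -0.140 in model C. Fewer cells of the mesenchymal kind in the lung of model C would raise luminal genes there relative to others. The luminal list was at -0.17 and the median of all tested genes at -0.46, so its value does not speak against this. Relative to that median in each mouse the list was at 0.27 ± 0.25 (SD) in C, -0.29 in A and -0.24 in B. The models did not differ after adjustment (exact permutation p = 0.0619, adjusted 0.356), and no test was run within model C. Fibroblast and pericyte markers fell with the mesenchymal genes, at -2.21. The cause of the fall is left open. Counting VIM-positive human cells in both tissues would test it.

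Relative to the median of all genes in each mouse, MYC targets of ribosome biogenesis were higher in lung by 0.42 ± 0.30 (SD) in 9 of 9 mice (exact sign-flip p = 0.0039, adjusted 0.0449 over 23 lists). The hypoxia list was lower by 1.39 on that scale, also with an adjusted p of 0.0449. This scale was added after the lists had been seen, and camera with an estimated correlation did not call the MYC list (adjusted p = 0.337). On the scale fixed in advance the MYC list was higher in 6 and lower in 3 mice, by a mean of 0.25 ± 0.35 (SD). It did not pass there (exact sign-flip p = 0.0664, adjusted 0.249). Measuring ribosomal RNA synthesis in cells of both tissues would test whether it differs.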
